A study of Homo sapiens with 18 samples.

How the data were processed

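MYC chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed from MCF10A cells, an immortalised, non-tumour breast epithelial line, that carried ectopic MYC and a mutant PI3K. Per the labels' protocols, doxycycline at 2 µg/mL for 72 h induced a scramble hairpin (shSCR) or 1 of 2 hairpins against the histone methyltransferase G9a (called shG9a_1 and shG9a_4 here, after the plasmid labels). Each immunoprecipitation used 10000000 cells and the homemade MYC antibody N262, and libraries were read as single 50 bp reads to a planned depth of about 25000000 reads per sample. The series holds 18 samples. The 9 MYC libraries (3 biological replicates per hairpin, per the series design) each have 1 peak list, and the 9 DNA inputs have no peak list used here.

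The submitters' processing notes name STAR 2.5.2a, SAMtools 1.3, Picard 2.7.1 and MACS2 2.1.0 and the builds GRCh37 and hg19, without saying which step each served. Peaks were listed per library, and replicates were not pooled, as the peak names in the deposited files show. The authors' lists give, for each peak, a whole-number score, which is 10 times the −log10 q-value with the decimals dropped in nearly every row. The deposited fold enrichment is a ratio of pileup to local background at the summit, each with 1 added. The deposited −log10 p-value and −log10 q-value are also taken at the summit, and the q-values were adjusted by the caller within each library. The highest listed q-value in any library was about 0.05. The settings of the caller and the filters on reads are not given in the sources used here. Fold, p and q are the authors' values. They served to describe, rank or filter peaks within a list and, through fold and p, to recover pileups and depths, which were compared between libraries.

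Read depth is not listed, so relative depth was recovered from the peak values. For a Poisson caller, a fold of (pileup + 1)/(background + 1) and its p-value fix a whole-number pileup, and 100% of the peaks in every list gave one within 0.001 on the −log10 p scale. The lowest background that at least 1% of the peaks of a library shared was divided by the library's shortest peak, taken as the fragment length, and expressed relative to the shSCR mean. Pileup over background is the recovered pileup divided by that lowest background of its library, with nothing added, and so differs from the fold. This assumes the same genome size setting in every library. If that setting was the caller's default for human, the recovered depth was 6.80 to 21.4 M fragments per ChIP library. On simulated values, 100% of pileups were recovered.

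The main analysis used chromosomes 1 to 22 and X, which left out 192 of 151062 peaks. All peaks of the 9 lists were merged where they overlapped by at least 1 bp, and a library called a region when 1 of its peaks overlapped it. A region was reproducible in shSCR when all 3 shSCR libraries called it. Such a region was lost when none of the 6 shG9a libraries called it, kept when at least 5 called it, and partial otherwise. A region was gained when no shSCR library called it and at least 2 of 3 libraries of each hairpin did. Region strength was the mean over the shSCR lists of the percentile of the best peak, ranked by q-value within its list. On 20000 simulated regions in 9 simulated libraries, 2000 of 2000 lost, 15000 of 15000 kept and 200 of 200 gained regions were recovered. These regions were planted without missed calls, so this checks the counting of states and not whether an uncalled region was unbound.

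Peak numbers were compared by two-sided exact permutation tests on libraries. Counts of lost regions were compared with those of other splits of the same libraries. For the overlap of the 2 hairpins' lost lists, which share their controls, 100 sets of unchanged libraries were simulated from the rate, by strength, at which each shSCR library called regions found in both others, and the overlap of independent lists was computed over all regions and within 50 strength classes. Shares of regions carry Wilson 95% intervals, which cover counting error only. The tests of peak number, the region states, the overlap of the hairpins' lost lists with independent and simulated lists, the alternatives and the rule for named regions were fixed before the data were examined. The sizes of the deposited files, which follow peak number, were known by then, and for that reason the setting with equal peak numbers left out shG9a_1 replicate 1 from the start. The rule took the 10 lost, 10 kept and up to 5 gained regions of highest strength, and no more than 4 regions were gained. Alternatives were stricter q-value and fold limits, other overlap rules, all sequences, covered length, equal peak numbers, a replicate block, and leaving out each library. Added after the data were seen were alternatives without shG9a_1 replicate 1 and with libraries of like depth, the overlap of lost lists at like strength, the widths of shSCR peaks, and the closing section's tests of depth, enrichment, equal-number lists, shG9a_1 replicate 1, chromosomes and neighbouring regions. Of these, the outcomes to be looked for in the tests of 1 enrichment factor, of an input label and a weak immunoprecipitation in shG9a_1 replicate 1, and of neighbouring regions were written down before their own values were seen.

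No gene annotation or genome sequence of the files' build was used here. Regions are therefore given by position, and the planned tests of promoter share, E-box share, promoter against distal loss and 15 gene lists were not run. No peak was identical in position, fold and p-value between any pair of lists, so all 9 libraries were counted separately. The G9a level in these cells was not analysed here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.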

Results

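MYC binding was profiled by ChIP-seq in MCF10A breast epithelial cells transformed by ectopic MYC and a mutant PI3K, 72 h after induction of a scramble hairpin or of 1 of 2 hairpins against G9a, a histone H3 methyltransferase. The peak lists of the 3 shSCR libraries held 29827, 34738 and 20118 peaks on chromosomes 1 to 22 and X. Those of shG9a_1 held 113, 11462 and 13068, and those of shG9a_4 held 11168, 17454 and 12922. Recovered ChIP depth, relative to the shSCR mean, was 1.04, 1.04 and 0.925 in shSCR, 2.36, 0.841 and 1.09 in shG9a_1, and 1.90, 1.05 and 2.65 in shG9a_4. The 2.36 of shG9a_1 replicate 1 rests on its shortest peak of 51 bp and would be 0.767 to 0.927 with the lengths of the other libraries. Median peak width was 223 to 275 bp in 8 libraries and 79 bp in shG9a_1 replicate 1, and the authors' median fold enrichment was 6.24 to 7.09 in all 9. Merging all lists gave 43222 regions, of which 14209 were called in all 3 shSCR libraries.

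The first comparison asked whether lowering G9a changes the extent of MYC binding. Fewer MYC peaks were called with G9a hairpins than with the scramble hairpin: 28228 ± 7440 (SD, n = 3) in shSCR against 11031 ± 5803 (SD, n = 6) in the shG9a libraries, a fall of 60.9%. Every shG9a list was shorter than the shortest shSCR list. Peaks covered 9.27 ± 3.00 Mb (SD, n = 3) in shSCR and 3.14 ± 1.76 Mb (SD, n = 6) in shG9a. Both differences had p = 0.0238 (two-sided exact permutation test), the smallest that the 84 splits of 9 libraries allow. Without shG9a_1 replicate 1 the shG9a mean was 13215 ± 2517 peaks (SD, n = 5; exact permutation p = 0.0357, the smallest possible with 56 splits). Leaving out 1 shSCR library gave differences of 16397 (replicate 1), 13941 (replicate 2) and 21251 peaks (replicate 3), each with exact permutation p = 0.0714, the smallest then possible. Among the 5 libraries of like depth, the 3 shSCR libraries held 28228 peaks on average, and shG9a_1 replicate 3 and shG9a_4 replicate 2 held 13068 and 17454. That set of libraries cannot give a p below 0.2.

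**Figure D1:**
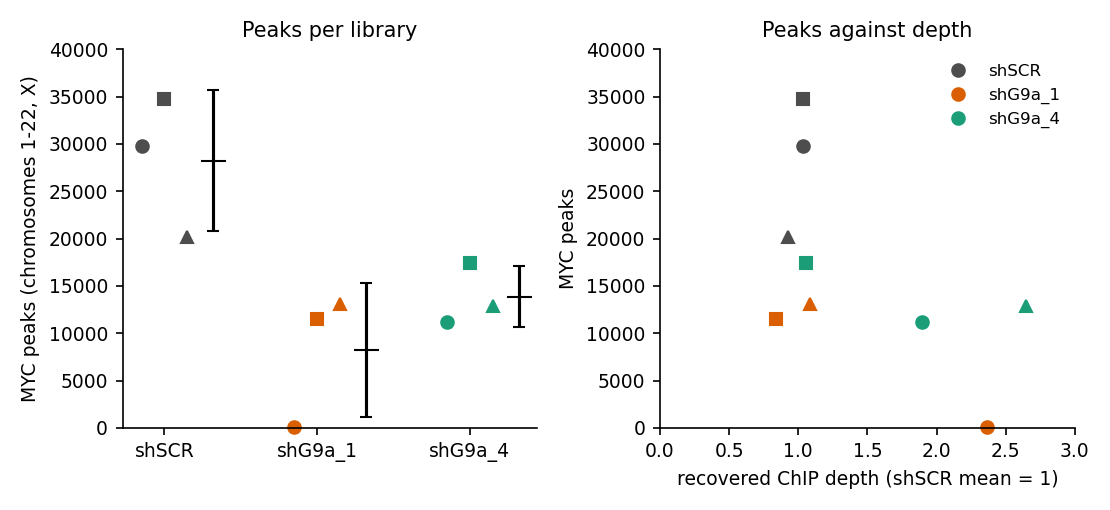
Number of MYC peaks on chromosomes 1 to 22 and X in each library (left; circle, square and triangle are replicates 1, 2 and 3, black bars are mean ± SD, n = 3) and against recovered ChIP depth relative to the shSCR mean (right). The shSCR libraries hold 20118 to 34738 peaks and the shG9a libraries 113 to 17454, and shG9a_4 replicates 1 and 3 are deeper than any shSCR library.

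The second question was which binding regions were no longer called. Of the 14209 regions reproducible in shSCR, 1348 (9.49%, 95% interval 9.02 to 9.98%) were lost from all 6 shG9a libraries and 5245 (36.9%, 95% interval 36.1 to 37.7%) were kept in at least 5. The remaining 7616 (53.6%) were partial. The kept regions were the same 5245 that all 5 shG9a libraries other than shG9a_1 replicate 1 called. Only 4 regions were gained. The count of lost regions depended on the libraries: it was 2228 without shSCR replicate 1, 5112 without shSCR replicate 3 and 2074 without shG9a_4 replicate 2. With each of 8 lists (without shG9a_1 replicate 1) limited to its 11168 top peaks, 79 of 6439 regions reproducible in shSCR were lost and 70 were gained. In that setting 5162 (80.2%) were kept, which there meant called in at least 4 of the 5 shG9a libraries. By that looser rule the full lists without shG9a_1 replicate 1 kept 7423 of 14209.

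Lost regions were the weaker and narrower ones. Weak peaks drop out first from a shorter list, whatever the cause, and every shG9a list was shorter than every shSCR list. This order therefore does not single out weak regions as dependent on G9a. Width is not a separate trait here, since median merged width rose from 382 bp in the weakest strength decile to 861 bp in the strongest. Their median fold in shSCR was 6.21, against 13.6 for kept regions and 7.75 for partial ones. The median width of their shSCR peaks alone was 235 bp, against 537 bp for kept and 315 bp for partial regions. In the weakest strength decile 39.6% of 1421 regions were lost and 0.844% kept. In decile 5, 5.21% were lost and 16.3% kept. In the strongest decile none was lost and 99.2% were kept. These shares describe listed peaks and do not cover binding under the caller's limit. The 5 shG9a libraries other than shG9a_1 replicate 1 each called 14.3 to 36.7% of the weakest decile and 99.6 to 100% of the strongest, while shG9a_1 replicate 1 called 0% and 7.32%.

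**Figure D2:**
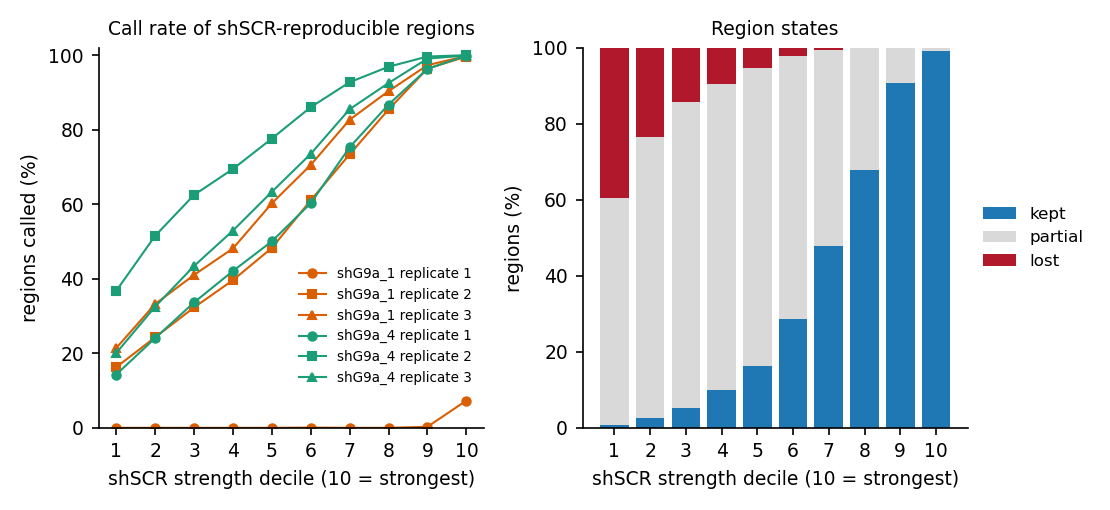
Share of shSCR-reproducible regions called in each shG9a library (left) and share of lost, partial and kept regions (right), by decile of region strength in shSCR. Lost regions make up 39.6% of decile 1 and 0% of decile 10, and kept regions 0.844% and 99.2%.

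The strongest lost regions lay on 9 chromosomes. The first was at chromosome 5, 121737948 to 121738449 (hg19, as are all positions here), with a fold of 13.1 ± 2.25 (SD, n = 3) in the shSCR lists. A region at chromosome 1, 218599057 to 218599368, had a fold of 11.2 ± 3.16 (SD, n = 3), and one at chromosome 3, 124553799 to 124554170, a fold of 11.2 ± 1.99 (SD, n = 3). The others were at chromosome 10, 24779971 to 24780267, chromosome 18, 45471885 to 45472230, chromosome 21, 29765626 to 29765979, chromosome 15, 53022438 to 53022720, chromosome 1, 228103462 to 228103749, chromosome 19, 7934035 to 7934416, and chromosome 6, 78944971 to 78945253. Mean folds of the 10 regions ranged from 9.72 to 13.1 and merged widths from 283 to 502 bp, and their strength percentiles in shSCR were 74.5 to 87.7. None was called in any shG9a library. The gene content of these regions was not analysed here.

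The 10 strongest of all shSCR-reproducible regions were kept regions, and each of these 10 was called in all 9 libraries. The first was at chromosome 7, 4681220 to 4682114, with a fold of 101.5 ± 31.7 (SD, n = 3) in shSCR. The region at chromosome 17, 42147795 to 42148704, had a fold of 73.8 ± 13.4 (SD, n = 3) and that at chromosome 5, 154134002 to 154135584, a fold of 63.6 ± 8.52 (SD, n = 3). The others were at chromosome 2, 70312984 to 70315163, chromosome 1, 222638708 to 222639412, chromosome 1, 245026090 to 245027137, chromosome 5, 170814338 to 170815998, chromosome 16, 21531382 to 21532266, chromosome 8, 145733531 to 145735369, and chromosome 14, 91883721 to 91885398. The 10 regions had mean shSCR folds of 52.7 to 101.5 and merged widths of 705 to 2180 bp. Kept means called and not equal in height: median pileup over background at the 5245 kept regions was 56.2 ± 6.40 (SD, n = 3) in shSCR and 31.4 ± 8.66 (SD, n = 5) in shG9a without shG9a_1 replicate 1 (two-sided exact permutation p = 0.0357, the smallest possible). The lowest medians, 22.6 and 22.3, were in shG9a_4 replicates 1 and 3, the deepest of these libraries. In the shG9a libraries of like depth to shSCR they were 35.3 (shG9a_1 replicate 3) and 42.0 (shG9a_4 replicate 2), against at least 51.5 in shSCR. Whether this measure varies with depth was not tested.

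**Figure D3:**
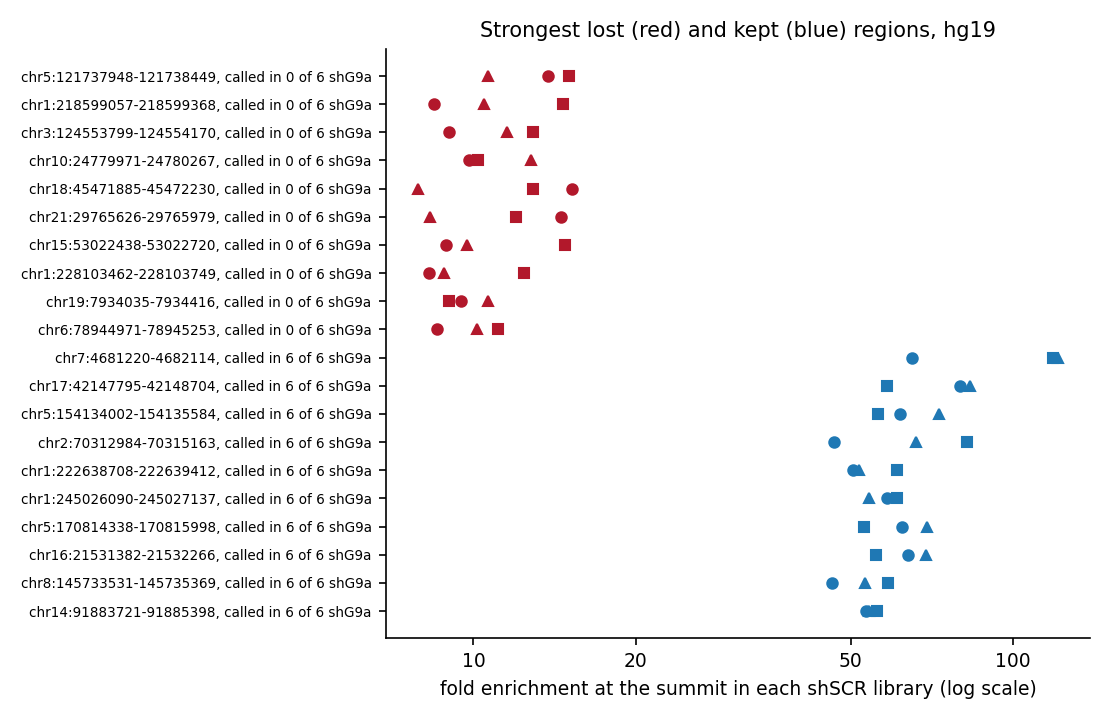
Authors' fold enrichment at the summit in each of the 3 shSCR libraries (log axis; circle, square and triangle are replicates 1, 2 and 3) for the 10 strongest lost (red) and the 10 strongest kept regions (blue). Mean folds are 9.72 to 13.1 for the lost regions, called in 0 of 6 shG9a libraries, and 52.7 to 101.5 for the kept ones, called in 6 of 6.

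The 4 gained regions were weak. They lay at chromosome 19, 18497482 to 18497880, chromosome 2, 227750543 to 227750789, chromosome 20, 343932 to 344435, and chromosome 19, 55728327 to 55728599. Each was called in 2 libraries of each hairpin, and their mean strength percentiles in the shG9a_4 lists were 10.0 to 39.3. Regions called in no shSCR library made up 2.11 to 5.35% of the regions called in the shG9a libraries other than shG9a_1 replicate 1, and none of the 109 regions called in that library. The gained count was 0 without shG9a_1 replicate 2 or replicate 3, 1 without shG9a_4 replicate 2 or replicate 3, 2 without shG9a_4 replicate 1, 7 without shSCR replicate 1 and 14 without shSCR replicate 2.

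Taken alone, shG9a_1 gave 8214 ± 7062 peaks (SD, n = 3), 29.1% of the shSCR mean, and 12265 ± 1136 (SD, n = 2) without replicate 1. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. Replicates 2 and 3 called 57.7% and 64.5% of the shSCR-reproducible regions and replicate 1 called 0.767%. With this hairpin 3601 regions (25.3%) were lost and 6747 (47.5%) were kept in at least 2 libraries. All regions of replicate 1 were also called in both other replicates, so it removed none from the lost list. The lost count was 8995 without shSCR replicate 3 and 6015 without shG9a_1 replicate 3, and the kept count was 109 without either replicate 2 or replicate 3.

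With shG9a_4 there were 13848 ± 3244 peaks (SD, n = 3), 49.1% of the shSCR mean (exact permutation p = 0.1, again the smallest possible). Its libraries called 58.3%, 77.3% and 66.3% of the shSCR-reproducible regions. In this hairpin 1922 regions (13.5%) were lost and 9772 (68.8%) kept in at least 2 libraries. The lost count was 2973 without shSCR replicate 1, 6286 without shSCR replicate 3 and 3480 without shG9a_4 replicate 2. At equal peak numbers 179 regions were lost with shG9a_4 (called in none of 3 libraries) and 427 with shG9a_1 (called in neither replicate 2 nor 3). With unlike numbers of libraries these 2 counts do not compare the hairpins.

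The last comparison set the 2 hairpins side by side. Of the 1922 regions lost with shG9a_4, 1348 (70.1%) were also lost with shG9a_1, whose longer list held 3601 regions. Independent lists of these sizes would share 487 of 14209, and independent lists at like shSCR strength 1001. Libraries simulated without any effect against the same controls lost 70.7 and 69.9 regions on average and shared 2.31. They called regions at the rates of the shSCR libraries, whose lists are longer, and independently at a given strength. Their counts therefore give no reference for how far the hairpins agree. Both hairpins' lost lists use the same 3 control libraries, which are too few to divide, so part of the excess over independent lists may come from them. Peak number in shG9a_1 less that in shG9a_4 was −5634 (two-sided exact permutation p = 0.5), and −1583 without shG9a_1 replicate 1 (p = 1, exact permutation test). The shG9a_1 lost list effectively rests on 2 libraries, and with 1 library of shG9a_4 left out that hairpin's list held 2300 to 3480 regions. There were 296 regions called in all 3 shG9a_4 libraries and no shG9a_1 library, and 72 called in shG9a_1 replicates 2 and 3 and no shG9a_4 library.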

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

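Mitochondrial peaks lie outside the chromosomes compared above and were looked at only after the lists were seen. The shSCR libraries listed 2, 0 and 0 of them. More than in any shSCR library were listed in shG9a_1 replicate 2, with 10 peaks, shG9a_4 replicate 1, with 8, and shG9a_4 replicate 2, with 15. None was listed in the 3 other shG9a libraries, so each hairpin had libraries with and without them. Their median folds were 2.16, 1.43 and 1.53 within their own lists, and they covered 13640, 2349 and 4798 bp. No explanation was tested.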

How the results depend on the processing

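The settings with libraries of like depth and without shG9a_1 replicate 1 throughout were chosen after the data were seen. The stricter overlap rule moves no count, by construction, since each peak lies within its merged region. No setting that was run changed a direction. The fall in peak number against both hairpins (17197 peaks) had an exact permutation p of 0.0238 with stricter q-value or fold limits, all sequences or covered length. With permutation within replicate numbers (replicate block) the same 17197 had p = 0.0741, the smallest possible, and with libraries of like depth 12967 had p = 0.2, also the smallest possible. Both settings allow fewer splits. Within replicate numbers 1 of 27 splits gave as many lost regions as the real 1348. That count follows list length and adds no separate support: the shSCR lists are the longest, and splits with shG9a_1 replicate 1 as a control gave 0. The numbers were not read as pairs: deviations from group means correlated at −0.0996 to 0.170 between same-numbered libraries and −0.283 to 0.214 between others, and not every library correlated best with its own number. Both ends of the latter range came from pairs with shG9a_1 replicate 1. Without that library, pairs of unlike number ranged from −0.122 to 0.122. Over all pairs the median was 0.0298 for like numbers and −0.0108 for unlike ones, so a weak pairing is not excluded. With a −log10 q of at least 5, 1 region was gained and 4344 were kept with shG9a_1. With equal peak numbers, shSCR-reproducible regions fell to 6439, lost regions to 79 (427 with shG9a_1, 179 with shG9a_4, 79 with both), kept regions with shG9a_4 to 5781, and gained regions rose to 70. That setting shortens the shSCR lists most, by construction. Leaving out 1 library at a time gave differences of 13941 to 21251 peaks for both hairpins, 15963 to 24068 for shG9a_1, 11125 to 18435 for shG9a_4 and −8061 to −1583 between hairpins. With any 1 shSCR library out, the exact permutation p for both hairpins was 0.0714, the smallest possible. The same exercise gave 14209 to 21233 shSCR-reproducible, 1348 to 5112 lost, 5246 to 7423 kept and 0 to 14 gained regions. With a shG9a library left out, kept still allowed 1 of the remaining shG9a libraries to miss the region. The 7423 was the count without shG9a_1 replicate 1 by that rule, and it was 5245 when every remaining library had to call the region. Per hairpin it gave 3601 to 8995 lost and 109 to 7004 kept with shG9a_1, 1922 to 6286 lost and 6968 to 10561 kept with shG9a_4, and 1348 to 5112 lost with both. The alternatives planned for promoter, E-box and gene list results were not run. Lists hold only peaks past the caller's limit, so a lost region is one that was not detectable at each library's depth and enrichment.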

Other observations

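The tests on depth (of all shG9a libraries and of shG9a_1 replicate 1), on chromosomes, on lost regions at equal peak number and on pileup over background were chosen after the results were seen. Chromosome X had the highest lost share, 14.2% of 212 regions, and the lowest kept share, 25.5%, with a median shSCR strength at the 58.5 percentile. The number of the 6 shG9a libraries that called its regions, less the number expected at like strength, was −0.179 on average. The same difference was −0.151 for chromosome 18, 0.141 for chromosome 13 and 0.111 for chromosome 16. No chromosome passed the test of whether retention differs between chromosomes at like strength, and the lowest adjusted p over 23 chromosomes was 0.143 (stratified permutation test, Benjamini-Hochberg). Regions with another shSCR-reproducible region within 10 kb (5225 of 14209) were called in 3.20 shG9a libraries on average, 0.0102 above the number expected at like strength (permutation p = 0.430), so a hypothesis that clustered sites keep MYC better was not borne out either. On unplaced contigs, 9 regions were called in all 3 shSCR libraries, of which 4 were kept, 5 partial and 0 lost. Kept ones included GL000220.1, 6925 to 8372, with a mean shSCR fold of 15.2, and GL000205.1, 84509 to 87931, with 12.4. The region at GL000220.1, 92897 to 93262, with 5.19, was called in 1 shG9a_4 library and no shG9a_1 library, and that at GL000219.1, 99522 to 100208, with 8.16, in 1 library of each hairpin.

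For the fewer peaks with both hairpins, 1 of the 84 splits gave as many as the real 1348 lost regions (highest other 770), so chance can be excluded only as far as for peak number, which this count follows: the 3 shSCR lists are the longest, and the 28 splits with shG9a_1 replicate 1 as a control gave 0. For single hairpins the 10 possible splits are too few for a share under 0.05 (1 of 10 in each case, 3601 against a highest other of 758 for shG9a_1 and 1922 against 1173 for shG9a_4). Lower depth is argued against, because shG9a_1 replicate 3 and all shG9a_4 libraries were deeper than every shSCR library, and thinning the shSCR libraries to the depth of shG9a_1 replicate 2 left at least 1.73 times its peaks. The margin was small for shG9a_1 replicate 3 (1.09) and shG9a_4 replicate 2 (1.05) against at most 1.04 in shSCR. In the deeper libraries, which needed no thinning, the lowest such ratio was 1.15 for shG9a_4 replicate 2 and 1.54 to 1.80 for the others. One lower enrichment factor in the shG9a immunoprecipitations and an effect of the G9a hairpins on MYC binding cannot be told apart, since pileup over background was 22.3 to 42.0 in the 5 shG9a libraries other than shG9a_1 replicate 1 and 51.5 to 63.5 in shSCR. At equal peak number a share of 0.0357 of the 56 splits had as low an overlap between groups relative to that within them, which met the bound set before that value was seen but decides nothing, because a mixed grouping went lower (−0.0113 against −0.0103), the overlap between groups (0.517) was above that within shG9a (0.507), and 79 lost regions (1 of 56 splits) compare with 74 for the highest other split and with 70 gained.

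The library shG9a_1 replicate 1 listed 113 peaks and its shortest peak was 51 bp, against 130 to 157 bp in the 8 others. Lower depth is argued against, since its recovered depth was 2.36 times the shSCR mean with the 51 bp length and would be 0.767 to 0.927 times with the lengths of the other libraries, of which shG9a_1 replicate 2, at 0.841, listed 11462 peaks. Peaks at random positions are argued against too: 100% of its peaks (95% interval 96.7 to 100%) lay in regions called by the other libraries, against 0.804% for randomly shifted peaks. That met the outcome written down beforehand against an input under this label. It does not exclude an input, because no input peak list was compared and input peaks need not lie at random. A weak immunoprecipitation and peak calling with a 51 bp fragment length, which was not tested, cannot be told apart. The median strength in shSCR of the regions of shG9a_1 replicate 1 was at the 99.5 percentile. That met the outcome written down for a weak immunoprecipitation before the value was seen. It decides nothing, because any cause of a short list of true peaks would leave the strongest regions.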
